A study of Mus musculus with 6 samples.

How the data were processed

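MicroRNA levels were measured in the abdominal aorta of 6 male ApoE-/- mice, 3 with Ang II-induced aneurysm (AAA) and 3 saline-infused controls, with 1 one-colour Agilent mouse miRNA array per mouse. Groups were taken from the sample titles. Per the labels' protocols, Cy3 was incorporated from 0.5 µg RNA; the extraction and labelling texts there describe globin reduction and cRNA amplification, steps usual for mRNA from blood, so the small-RNA labelling actually used is not given in the sources used here. Per the submitters' processing notes and the file headers, the scans were read with Agilent Feature Extraction 10.7.1.1. The deposited scanner files give an intensity per spot, background-subtracted and detrended within the array, per the file headers, with no scaling between arrays, together with flags of 0 or 1 for spots well above background, saturated spots and outlier spots. The headers name the genome build mm9, and coordinates below are the mapped positions of probes in that build. No genome sequence was used.

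The authors also deposited a table of log2 values per miRNA, the same in the series' value table. In these deposited log2 values every array has the same distribution, which is quantile normalization, with the lowest value at -3.32, the log2 of 0.1; no label or header describes the step. The median over all 1881 miRNAs is at that lowest value on each array, and the median over miRNAs detected on all arrays is 5.79 to 5.89. The raw intensity columns of that authors' table equalled, within a relative tolerance of 0.01, the sum of the total signals of the detected probes of each miRNA on all arrays. The scanner files' own total per miRNA departed from that sum for 107 to 124 miRNAs per array and served only as an alternative. Another 24925 of the table's 26827 rows carry identifiers that are on none of the 6 arrays and were not used.

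Each array holds 56430 miRNA spots for 4415 probes and 1881 mouse miRNAs. Spots with outlier flags were left out, and the remaining spots of a probe were averaged on the linear scale. A probe counted as detected where at least 0.5 of its kept spots were well above background. Signals were divided by the array's 75th percentile over the 531 probes detected on all 6 arrays, then raised to a common floor of 0.0572 (the median over arrays of percentile 1 of the scaled signals of detected probes) and taken to log2. A level of 0 is therefore the 75th percentile of an array. A miRNA took the level of its brightest probe. Of 305 tested miRNAs with more than 1 detected probe, 24 had a probe with a difference of the other sign. No spot was saturated. The signal of a miRNA with no detected probe in a group is not well above background, so its difference is given as a bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest detected signal and its own.

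miRNAs detected on at least 3 of the 6 arrays were tested (419, of which 6 lay at the floor on every array, leaving 413) with limma 3.58.1 in R 4.3.3, lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fixed miRNA lists with at least 3 tested members (13 of 19) were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. The lists cover cell types an aortic sample can hold (smooth muscle, striated muscle, myeloid, lymphoid, erythroid, endothelial, adipose, liver and kidney, epithelial, neural and Schwann), miRNA families and clusters, miRNAs linked to Ang II, hypoxia or aneurysm in published work, and high-GC probes as a technical list. 10 miRNAs stand in more than 1 list. Single values per array were compared with exact permutation tests, two-sided, which cannot go below p = 0.10 for 3 against 3. The names of genes that hold a miRNA come from the RefSeq table of assembly GRCm38.p6, used for names and neighbours alone.

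The lists, their tests, the tests of single miRNAs, most alternatives and the rule for named miRNAs were fixed before the data were examined. Alternatives and further tests chosen after seeing the data are named in the closing sections. Since fewer than 20 miRNAs passed, the rule named all that passed, filled to 12 higher and 12 lower by p among miRNAs whose groups did not overlap, up to 4 members of each list by p, 20 miRNAs studied in vascular disease where tested, and up to 10 miRNAs detected in 1 group alone. The alternatives covered scaling, background correction, probe summary, the authors' log2 values, the filter, the floor, the test, a replicate block, array weights and the omission of each array. Under other scalings that moved the median of all miRNAs by over 0.1 on the log2 scale, differences of named miRNAs were read relative to that shift. Their adjusted p stayed that of the unshifted fit. The fit was tested on simulated data built on the means and spreads of the 413 miRNAs with 60 of them changed: it recovered 92.8% of 4-fold changes and 52.4% of 2-fold changes, with 4.40% and 2.70% false calls, and made 0 calls per run with no change. The simulated noise was normal and independent between miRNAs and arrays, with no floor and no outlying array. These rates therefore need not hold for the real arrays, whose miRNAs are correlated. The number of arrays limits the precision.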

Results

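The arrays addressed which miRNAs differ in the abdominal aorta of mice with an Ang II-induced aneurysm. Male ApoE-/- mice, which lack apolipoprotein E and are prone to atherosclerosis, were infused from 8 weeks of age with Ang II at 1000 ng/kg/min (AAA, n = 3) or saline (control, n = 3) by osmotic pump for 28 days. Ang II infusion in this strain is a standard model of abdominal aortic aneurysm. Levels are log2 values relative to the 75th percentile of each array, given as mean ± SD over 3 mice, and differences are AAA minus control ± SE.

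More miRNAs were detected in AAA than in control aortas. The AAA arrays detected 438 ± 16.7 of 1881 miRNAs (SD, n = 3) and the control arrays 343 ± 26.5 (SD, n = 3), with 425 to 457 and 322 to 373 per array (exact permutation test, p = 0.10, the smallest this design allows). The AAA arrays were also brighter before scaling: the 75th percentile of probes detected on all arrays was 404 ± 65.5 scanner units in AAA and 243 ± 15.8 in controls, a difference of 0.72 on the log2 scale (exact permutation p = 0.10). The 2 labelling spike-in RNAs, which are added in fixed amount before labelling, had means of 688 ± 20.9 and 686 ± 127 units, and the hybridization spike-ins differed by 0.41 on the log2 scale (exact permutation p = 0.60). All 6 arrays lay on 1 slide read in 1 scan, with the AAA arrays in one row of the slide and the control arrays in the other, so position on the slide and group cannot be told apart. Correlations of the tested miRNA levels across miRNAs, which are not independent replicates, were 0.979 to 0.993 within AAA and 0.913 to 0.978 within controls. Between the groups they were 0.916 to 0.955. Control 2 correlated with controls 1 and 3 at 0.920 and 0.913, no better than with the AAA arrays, at 0.921 to 0.936.

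**Figure D1:**
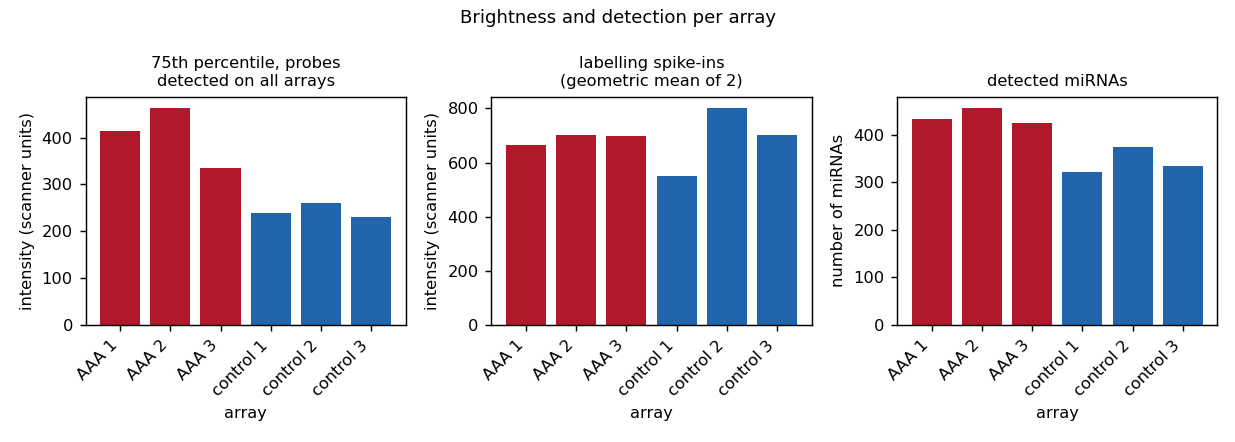
Bars give, for each of the 6 arrays, the 75th percentile of probes detected on all arrays (scanner units), the geometric mean of the 2 labelling spike-ins (scanner units) and the number of detected miRNAs. The AAA arrays detected 425 to 457 miRNAs and the control arrays 322 to 373, while the spike-ins of both groups overlap.

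miR-21a-5p, an abundant miRNA induced in many injured and fibrotic tissues, was higher in aneurysmal aortas. Its level was 4.56 ± 0.21 in AAA and 3.25 ± 0.25 in controls, a rise of 1.31 ± 0.26 or 2.47-fold (limma, adjusted p = 0.0479), and it was higher in each AAA mouse than in any control. miR-762 passed as higher, by 1.20 ± 0.17 (adjusted p = 0.0335), but was detected on 1 control array only, so the size of the difference depends on the floor. Over 22 alternatives it ranged from 0.31 to 2.11 (adjusted p 6.80e-04 to 0.752). This miRNA belongs to the technical high-GC list, of which no other member rose, and 1 of its 3 detected probes had the other sign. miR-6963-5p was well above background on all AAA arrays and on no control array, at least 3.07-fold higher in the levels used here (limma adjusted p = 0.0444). Over 22 alternatives its log2 difference ranged from 0.63 to 3.44 (limma adjusted p 3.32e-07 to 0.179), and it passed in 11. Among the 6 that fell were miR-30a-3p, the passenger strand of a miRNA abundant in heart and kidney, by 1.37 ± 0.26, and miR-149-5p, by 0.86 ± 0.16 (adjusted p = 0.0444 for both). Over 23 alternatives miR-30a-3p ranged from -1.55 to -0.60 and passed in 8. The range of miR-149-5p was -1.39 to -0.20, and it passed in 9.

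Of 413 miRNAs tested, 3 rose and 6 fell in AAA in limma's test, and 99 had an unadjusted p under 0.05. The other 4 that fell were miR-7682-3p, miR-129b-5p, miR-6904-5p and miR-6918-5p, by 1.23 to 1.31 on the log2 scale. Over 23 alternatives their differences lay between -1.64 and -0.17, and each passed in 9 to 12. In all, 128 miRNAs (31.0%) had groups that did not overlap, where chance gives 10% on average over splits. The miRNAs are not independent and the share in other splits was not computed, so the excess over 10% is no test. Probe positions in mm9 were chromosome 11, 86397588 to 86397607 for miR-21a-5p, chromosome 1, 94746964 to 94746980 for miR-149-5p and chromosome 1, 23279160 to 23279175 for miR-30a-3p. In the RefSeq table miR-21a lies within the span of Vmp1, miR-149 within Gpc1, miR-6904 within Parp1, miR-6963 within Itga5 and miR-762 within Bcl7c. The count depended on single arrays: without control 2 it was 108 (54 higher, 54 lower, all 9 among them), without AAA 3 it was 2, and without any other single array it was 0, with 52 to 85 at an unadjusted p under 0.05. It also depended on scaling, since with none between arrays, where the median difference was 0.71, 228 miRNAs were higher and 0 lower, against 9 and 8 with quantile normalization and 4 and 134 with normexp background correction.

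**Figure D2:**
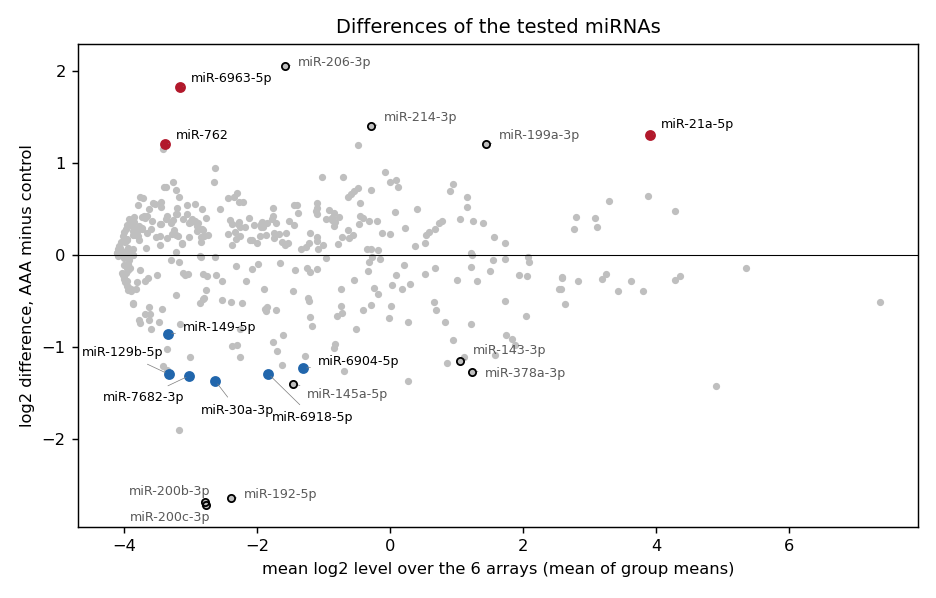
Each point is 1 of the 413 tested miRNAs, with its mean log2 level on the x axis and the log2 difference AAA minus control on the y axis; red and blue points passed adjusted p 0.05 in limma, and open black circles mark other named miRNAs. miR-21a-5p stands apart as an abundant miRNA that rose, by 1.31.

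The miRNAs closest to the threshold were mostly lower in AAA, and none of them passed. miR-7022-3p had a difference of -0.63 ± 0.13 (limma adjusted p = 0.0531), miR-30e-3p of -1.21 ± 0.25 and miR-504-3p of -0.99 ± 0.21. The abundant miR-6366, a member of the technical high-GC list, had levels of 4.19 ± 0.18 and 5.61 ± 0.47. On the higher side, miR-6998-5p differed by 0.79 ± 0.17 (adjusted p = 0.0540) and miR-7036a-5p by 0.85 ± 0.25 (adjusted p = 0.110).

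miR-199 and miR-214 miRNAs, which are abundant in fibroblasts and other mesenchymal cells, were higher in AAA as a list at camera's preset correlation, while no member passed alone. All 4 tested members had positive differences, led by miR-214-3p at 1.40 ± 0.41 (levels 0.42 ± 0.53 and -0.99 ± 0.70), with 1.20 for both miR-199a-5p and miR-199a-3p and 0.90 for miR-199b-5p. 0 of 4 passed over all miRNAs and 4 of 4 adjusted over the list alone. As a list they were higher than the other miRNAs (camera, adjusted p = 0.0152), a call lost with an estimated correlation (adjusted p = 0.465) and without control 2 (adjusted p = 0.138), and past the threshold in 13 of 22 alternatives (adjusted p 1.09e-04 to 0.465). Mir214 and Mir199a-2 lie within Dnm3os, and the miR-214-3p probe maps to chromosome 1, 164153579 to 164153590 (mm9).

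The smooth muscle pair miR-143-3p and miR-145a-5p, which promote the contractile state of vascular smooth muscle, had negative differences of -1.15 ± 0.30 and -1.40 ± 0.32 (limma, adjusted p = 0.0836 and 0.0628). Both passed adjusted over the list alone and neither over all miRNAs; only 2 of the 7 listed miRNAs were tested, so the list had no set test. The miR-143-3p level was 0.48 ± 0.01 in AAA and 1.62 ± 0.54 in controls. Both lie within the non-coding gene Carmn on chromosome 18, with probes at 61808895 to 61808909 and 61807494 to 61807507 (mm9). Their mean level on control 3 was 1.08, against 0.15 and 0.05 on the other controls and -0.92 to -0.81 in AAA.

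miRNAs of adipose tissue were lower as a list in AAA, with all 8 tested members negative and a mean difference of -0.87 ± 0.38 (SD over members; camera, adjusted p = 8.56e-04; adjusted p = 0.465 with an estimated correlation). The list passed in 19 of 22 alternatives. The largest member difference was miR-378a-3p, encoded within Ppargc1b, at -1.26 ± 0.29 (levels 0.60 ± 0.17 and 1.87 ± 0.49), followed by miR-455-3p at -1.24 and miR-378a-5p at -1.19. 0 of 8 passed over all miRNAs and 4 adjusted over the list alone. The controls also differed among themselves, with a list mean of -0.61 on control 3 and -1.37 and -1.47 on controls 1 and 2.

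The miR-17-92 and paralogous clusters, which are linked to cell proliferation, had 8 of 8 tested members lower, by a mean of 0.60 (camera, adjusted p = 0.00245; adjusted p = 0.465 with an estimated correlation). miR-92a-3p differed by -0.92 ± 0.31 and miR-106b-5p by -0.66 ± 0.25, and 0 passed over all miRNAs or adjusted over the list alone. The list passed in 18 of 22 alternatives (camera adjusted p 1.75e-04 to 0.465). Its mean difference against the other miRNAs was -0.61 over all arrays and -0.39 without control 1 (camera, adjusted p = 0.0162). The miR-29 family, whose targets include collagen and elastin transcripts, had 4 of 4 tested members lower, with miR-29c-3p at -0.72 ± 0.30, or -0.47 without control 3, and miR-29b-3p at -0.60 ± 0.32 (camera, adjusted p = 0.0312; adjusted p = 0.465 with an estimated correlation). 1 member, miR-29c-5p, passed adjusted over the list alone, and miR-29b-3p was at -0.92 without control 2 (limma adjusted p = 0.0247, and 0.0247 to 0.834 over 23 alternatives). Without AAA 3 or control 3 the list gave camera adjusted p = 0.118 and 0.0821. Its mean difference against the other miRNAs shrank from -0.60 to -0.40 without control 3. The list passed in 6 of 22 alternatives (camera adjusted p 0.0172 to 0.572). The lymphoid list had 5 of 5 members lower, led by miR-150-5p, abundant in mature lymphocytes, at -1.26 ± 0.42 and miR-181a-5p at -0.80 ± 0.22 (camera, adjusted p = 0.0309; adjusted p = 0.465 with an estimated correlation). These 2 passed adjusted over the list alone, and without control 1, the array on which this list was highest, or AAA 3 the list had camera adjusted p = 0.118 and 0.0658 (range over 22 alternatives 0.0139 to 0.465). Its mean difference against the other miRNAs was -0.61 over all arrays and -0.39 without control 1.

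**Figure D3:**
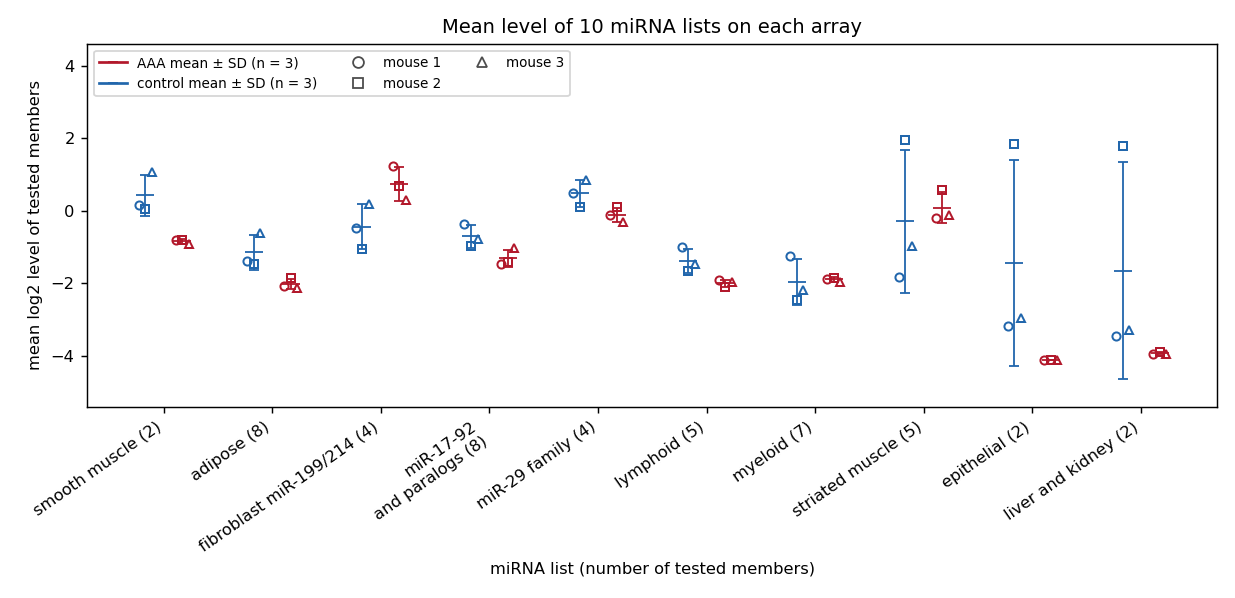
Points give the mean log2 level of the tested members of 10 miRNA lists on each array, with the number of members in brackets; dashes and bars are group means ± SD (n = 3). The smooth muscle and adipose means are lower on every AAA array than on every control array, and control 2 stands apart in the epithelial list (1.84) and the liver and kidney list (1.79).

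miRNAs of other tissues varied most between the control mice. The epithelial miR-200b-3p and miR-200c-3p were well above background on all control arrays and on no AAA array, at least 9.19-fold and 9.23-fold higher in controls (limma adjusted p = 0.264 and 0.197). Most of that gap came from control 2, where the list mean was 1.84 against -3.18 and -2.96 on controls 1 and 3. Without control 2 the log2 differences of miR-200b-3p and miR-200c-3p were -0.88 and -1.23 (limma adjusted p = 0.0132 and 0.00451). The size of the bounds therefore rests on that array. The same array led in miR-192-5p and miR-194-5p, which are abundant in kidney, liver and gut, with a mean of 1.79 against -3.46 and -3.28, and in the striated muscle list, at 1.94 against -1.83 and -0.97. miR-122-5p, the main miRNA of hepatocytes, was detected on no array, and neither was the epithelial miR-205-5p. The muscle miRNAs miR-1a-3p and miR-133a-3p differed between groups by -0.13 ± 0.83 and 0.00 ± 0.88. Both values depended on single controls, at 0.83 and 1.07 without control 2 and -0.97 and -0.85 without control 1, and neither passed in any of 23 alternatives. miR-206-3p was detected on 3 AAA arrays, at -0.87 to 0.05, and among controls on control 2 alone, at 0.41, so the size of its group difference depends on the floor and is not given.

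Myeloid, erythroid and endothelial miRNAs showed no difference that passed. Of 7 tested myeloid members, 3 were higher and 4 lower (camera, adjusted p = 0.661), with miR-223-3p, a neutrophil and monocyte miRNA, at 0.82 ± 0.31, or 0.51 without control 2, and miR-142a-3p at -1.01 ± 0.65, or -0.26 without control 1. miR-155-5p (-0.03 ± 0.34) and miR-146a-5p (-0.15 ± 0.32), both induced in inflammation, differed by less than their error and turned to 0.34 and 0.19 without control 1, and 1 detected miR-155-5p probe had the other sign. The erythroid miR-451a differed by -0.07 ± 0.59, in a list of 2 with a mean of -0.33, and by -0.67 without AAA 3 and 0.37 without control 3. The endothelial miR-126a-3p differed by -0.28 ± 0.31, and by -0.54 without control 2 and -0.01 without control 3. The neural and Schwann cell miRNA miR-338-3p, at -1.11 ± 0.37, passed adjusted over the list alone, which held 2 tested members with a mean of -0.63.

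Among 18 tested miRNAs linked to aneurysm in published work, 1 rose over all miRNAs (miR-21a-5p), 4 were higher and 14 lower. Adjusted over the list alone, miR-21a-5p, miR-143-3p and miR-145a-5p passed. miR-24-3p (-0.36 ± 0.33), miR-195a-5p (-0.05 ± 0.31), miR-181b-5p (-0.46 ± 0.21), miR-103-3p (-0.75 ± 0.25) and miR-712-5p (-0.43 ± 0.20) did not; 1 of the 2 detected miR-712-5p probes had the other sign. Without control 3, miR-24-3p was at -0.09 and miR-195a-5p turned to 0.19. As a list they gave camera adjusted p = 0.165, and 0.0310 without control 2 (range over 22 alternatives 0.0310 to 0.906). The list of Ang II and hypoxia responsive miRNAs held 6 tested members with 1 rise, again miR-21a-5p (camera, adjusted p = 0.789). In this list miR-212-3p was at -0.56 ± 0.20. miR-132-3p, detected on 1 control array only, was at 0.28 ± 0.23, a size that depends on the floor. It was at 0.12 without AAA 1 and 0.50 without AAA 3.

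The Dlk1-Dio3 cluster, an imprinted cluster of miRNAs, had 10 of 11 tested members higher (camera, adjusted p = 0.0773, 0.00190 without control 3, and 0.00190 to 0.776 over 22 alternatives). Its member miR-379-5p was at 0.95 ± 0.33 and kept its direction in 22 of 23 alternatives. With the scanner files' own total per miRNA it turned to -4.06. The let-7 list had 1 of 9 members higher (camera, adjusted p = 0.304, 0.0449 without control 2, and 0.0449 to 0.948 over 22 alternatives, 20 of them in the same direction). miR-34a-5p, a p53 target, was at 0.74 ± 0.31 in a list of 3 (adjusted p = 0.661). The striated muscle and high-GC lists gave camera adjusted p = 0.789 and 0.661, and the first gave 0.0449 without control 2 (range over 22 alternatives 0.0449 to 0.996). The high-GC list had camera adjusted p of 0.0298 to 0.996 over 22 alternatives and passed in 1, normexp background correction. For the striated muscle, myeloid, and Ang II lists the median and the mean of the members differed in sign. Over all 13 lists tested with camera, 1 passed as higher and 4 as lower, and 0 passed with an estimated correlation (0 at an unadjusted p under 0.05) or in fry's directional test (2 at an unadjusted p under 0.05). In fry's mixed test, which asks whether members change in either direction and does not compare a list with other miRNAs, the Ang II and hypoxia, aneurysm-linked, lymphoid and high-GC lists passed, 4 in all (adjusted p 0.00164 to 0.0212).

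**Figure D4:**
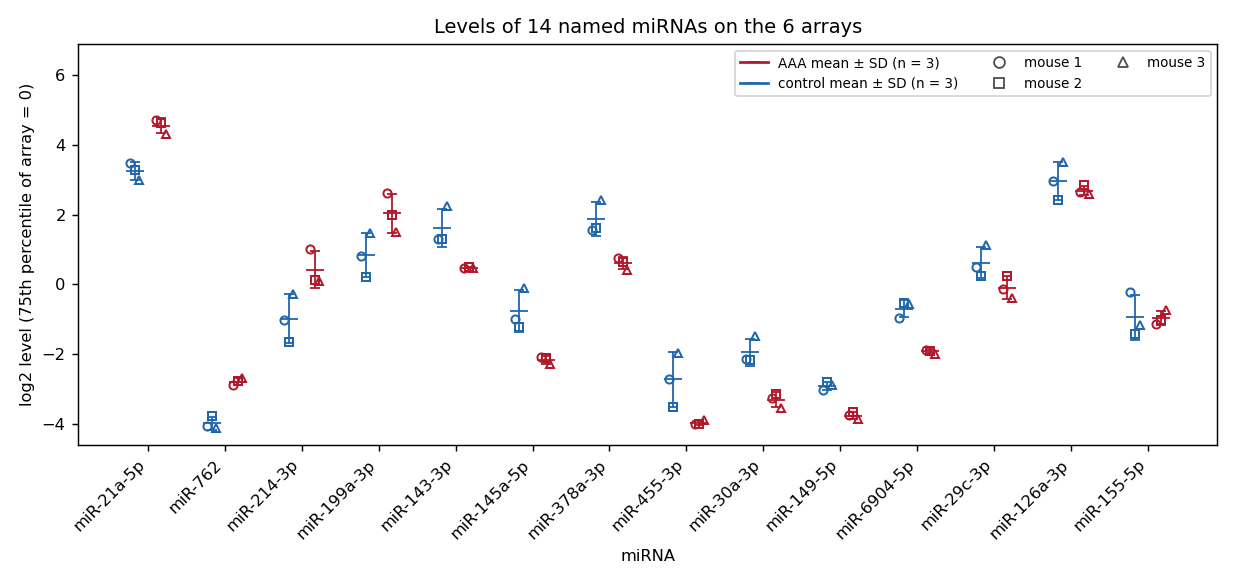
Points give the log2 level of 14 named miRNAs in each mouse, relative to the 75th percentile of its array; dashes and bars are group means ± SD (n = 3). miR-21a-5p lies higher in every AAA mouse than in every control, miR-143-3p and miR-145a-5p lie lower, and miR-155-5p overlaps.

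In all, 33 miRNAs were detected on every AAA array and on no control array, and 2 the other way, the miR-200 pair. A bound above 1-fold was possible for 10 of the 33. Besides miR-6963-5p the highest were miR-146b-5p, an inflammation-linked miRNA, at least 2.04-fold higher (limma adjusted p = 0.136), and miR-299b-5p of the Dlk1-Dio3 region, at least 1.38-fold higher (adjusted p = 0.126). These bounds hold for the levels used here. Over 22 alternatives the log2 differences of miR-146b-5p and miR-299b-5p ranged from -0.92 to 1.62 and from 0.03 to 2.79. The AAA arrays were the brighter ones, and without control 2 the number of such miRNAs was 80 in place of 35.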

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

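The gene-by-gene array weights, the scaling on labelling spike-ins, the sum of detected probe totals, normexp with quantile normalization, and the omission of arrays for the detection counts were chosen after seeing the data. The 9 miRNAs past the threshold in limma became 17 with quantile normalization, 228 with no scaling between arrays, 219 with scaling on the labelling spike-ins (218 higher, 1 lower), 138 with normexp, 5 with normexp and quantile normalization, 0 in the authors' processed values (106 at an unadjusted p under 0.05), 3 with no filter, 27 among miRNAs detected on all 6 arrays (2 higher, 25 lower), 0 with a 2 times higher floor (69 at an unadjusted p under 0.05), 138 with array weights estimated gene by gene (59 higher, 79 lower; limma's default estimator stopped before it converged, at 66 higher and 80 lower), and 30 at an unadjusted p under 0.05 with a 2-fold change (7 higher, 23 lower). Leaving out each array gave 0 to 108. The remaining 6 alternatives gave 6 to 11, with 2 to 9 of the main 9 among them. The fewest, 2 of 11, came with the scanner files' own total per miRNA. In normexp the offset of 50 is divided by each array's own scale, which lowers dim miRNAs on the brighter AAA arrays; with no scaling or spike-in scaling the brighter arrays give the rise; for the others the cause was not tested. No scaling, spike-in scaling, normexp and the authors' values moved the median difference of all miRNAs from 0.11 to 0.71, 0.70, -0.17 and 0.25. The replicate number as a block, which joins different animals, gave 25 miRNAs (6 higher, 19 lower) and 2 lists; deviations from the group means of same-numbered mice correlated at 0.30, -0.08 and -0.50, so the numbers do not pair them, and no AAA array's deviations correlated best with those of its own number. The 5 lists past the threshold in camera became 3 with the percentile over all probes, 2 with quantile normalization, 3 with no scaling, 2 with normexp, 3 among miRNAs detected on all 6 arrays, 3 with spike-in scaling, 3 with the sum of probe totals, 2 with normexp and quantile normalization, 0 with an estimated correlation and 0 in fry's directional test, which does not compare a list with other miRNAs; leaving out each array gave 3 to 7. With normexp the 2 lists that passed were both higher, 1 of the 5 and the technical high-GC list, and 0 passed as lower. The 5 lists kept their direction against the other miRNAs in all 22 alternatives each. For the 87 named miRNAs, directions were read relative to any shift of the median, while the adjusted p stayed that of the unshifted fit. Of 1963 values, 1573 kept direction and side of the threshold, and 112 lost and 192 gained it in the same direction. Another 85 changed sign without passing, and 1 reversed and passed: miR-379-5p, at -4.06 with the scanner file's total gene signal. Of the 192 gains, 28 came with no scaling, 25 with spike-in scaling and 19 with normexp, where the shift itself enters the adjusted p. The 85 came from 33 miRNAs, 22 of them under that signal, where miR-127-3p was at -3.23, and 15 under normexp; of 285 list values 19 changed sign without passing. miR-21a-5p stayed higher in 23 of 23, at 1.18 to 1.68, and passed in 12. The difference in detected miRNAs was 79.7 with all spots required, 92.3 with the file's own call and 84.3 to 110 with an array left out; the 35 miRNAs detected in 1 group alone were 32 with all spots required and 37 to 80 with an array left out. A slide or scan block was not run, since there was 1 of each. Signal over background limits dim miRNAs, whose differences the floor bounds.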

Other observations

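The tests in this part were chosen after the results were seen, except those on other splits of the arrays; the omission of control 3 was planned, and its use as a test here was not. The miR-30 family, abundant in heart, kidney and adipocytes, had 10 tested members, of which miR-30c-1-3p was detected on no control array, so that its direction is open; the other 9 were lower in AAA, with a mean difference of -0.86 ± 0.39 (SD over members): miR-30c-5p differed by -1.17 ± 0.30 and miR-30e-5p by -0.97 ± 0.27. The miR-378 family had all 5 tested members lower, by -1.12 ± 0.11. Families were grouped by the number in the miRNA name, and 13 had 3 or more tested members. With camera's preset correlation the adjusted p was 3.85e-05 for these 9 and 5.17e-04 for miR-378, and 4 families passed, while 0 of 13 passed with an estimated correlation (adjusted p = 0.625 for both), and 0 had an unadjusted p under 0.05 there, so that the test does not settle whether families moved together. Relative to all other tested miRNAs, both families stayed lower in 23 of 23 alternatives, by -1.57 to -0.45 for miR-30, with 7 to 10 members tested.

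The AAA arrays were brighter before scaling, by 0.72 on the log2 scale at the 75th percentile. Labelling and scanning efficiency would brighten the labelling spike-ins alike, but after division by them the difference was 0.70 ± 0.20 (SE), with every AAA array above every control array. A background or detection limit as the whole cause would spare bright probes, but the probes detected on all arrays whose mean signal lay at or above the 75th percentile still differed by a median of 0.57 ± 0.14. Over all 531 probes detected on all arrays the median difference was larger, at 0.84. A background or detection limit as part of the cause therefore stays open. The hybridization spike-ins were brighter in AAA by 0.41 (exact permutation p = 0.60), and 5 other bright control probes of the array, whose targets are not given in the sources used here, differed by a mean of 0.21 ± 0.19 (SD over probes). The amount or quality of the RNA, the slide row, which coincides with the groups, and a higher share of miRNA in aneurysmal tissue all stay open, the last untested.

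Control 2 carried miRNAs of other tissues. The lead did not rest on a single spot or probe. Of 20 probes of the epithelial and the liver and kidney lists detected on control 2, 14, from 8 miRNAs, exceeded both other controls by 1 on the log2 scale. These lists drew attention to the array and the probes were picked by detection on it, so the share is no test. The count also replaced an earlier bound on the share of such probes, which had left the question undecided. Liver tissue would bring miR-122-5p, whose brightest probe had an intensity of 4.40 on control 2, not detected, where miR-192-5p had 1478. All 4 tested members of these lists led on control 2 by 1 or more, but these miRNAs drew attention to the array, so their lead is no test of kidney or epithelial tissue near the aorta. That source and a difference between mice stay open, and the striated muscle list was also highest there.

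The mean differences of the adipose and smooth muscle miRNAs were negative and that of miR-199 and miR-214 was positive. No member passed over all miRNAs, and the smooth muscle pair had no set test. The other lists did not pass with an estimated correlation (camera, adjusted p = 0.465 for both). Less adipose tissue as the whole cause would raise all other tissues' miRNAs alike. The smooth muscle mean minus the fibroblast mean within arrays differed by -2.45 ± 0.27 (SE). These lists were compared after their opposite differences were seen, so the value restates the pattern and is no separate test of that cause. A further limit is that adipocytes also express miR-143. Intensity-dependent differences that equal distributions would remove are argued against by the contrast of fibroblast against smooth muscle and adipose miRNAs. It was 2.25 ± 0.29 in the levels used and 2.28 ± 0.30 and 2.34 ± 0.36 under quantile normalization and in the authors' values. Under normexp the contrast was not computed. There the adipose difference against the other miRNAs was -0.48 (camera adjusted p = 0.183), or -0.52 with quantile normalization added (camera adjusted p = 0.00285). A dependence on background treatment therefore stays open. Without control 3 the adipose difference against the other miRNAs shrank from -0.88 to -0.59, with a camera adjusted p of 0.00190 (adjusted p = 0.465 with an estimated correlation over all arrays), and controls 1 and 2, at -1.37 and -1.47, still lay above every AAA array, at -2.13 to -1.86, which argues against control 3 alone. A change in cell composition or in miRNA expression with the aneurysm, and fat or other tissue trimmed differently from the 2 groups, stay open, the first untested.

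For the 9 miRNAs, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many, and the highest of the others gave 0. For the 5 lists, 6 of the 10 splits, the real one included, gave as many, and the highest of the others gave 7. A design of 10 splits cannot give a share under 0.05. For the lists the share was far above that, since splits that mix the groups gave 3 to 7 lists. The number of lists past camera's threshold therefore does not set the real grouping apart.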
